A study of Zea mays with 6 samples.

How the data were processed

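RNA was sequenced from the developing 11th leaf, still wrapped inside the older leaves, of maize plants at vegetative stage 8. The labels describe 6 strand-specific libraries of total RNA depleted of ribosomal RNA, 3 from wild type and 3 from the hda108 mutant, as biological replicates. HDA108 encodes a histone deacetylase, an enzyme that removes acetyl groups from histones.

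The deposited values were FPKM (fragments scaled by transcript length and by the number of mapped fragments), with 1 value per gene and genotype, made by the authors from the libraries of that genotype. The submitters' processing notes name CASAVA 1.8, Trimmomatic 0.33, TopHat2 2.0.13, SAMtools, Cufflinks and Cuffdiff 2.2.1 and the genome build B73 RefGen_v3. They give no role, order or settings for these tools in the sources used here, so any scaling between libraries is unknown. The mutant column is named as homozygous and was read as the hda108 mutant, the other genotype in the labels. The sequencing depth behind the values is unknown. Among 200 genes with a mean below 0.02 FPKM, no ratio of the genotypes was shared by more than 3 genes, so the low values gave no whole-read steps from which depth could be taken.

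The tests planned before the data were examined used the spread between replicates (limma, with camera and fry for gene lists). They could not be run, because the table holds 1 pooled value per genotype. No difference below therefore has a replicate check, and no p-value, SD or n is given. A rule of size took the place of the test, chosen after the table had been seen: the log2 difference of FPKM + 0.5, hda108 minus wild type, had to reach 1 in either direction (2-fold). Folds on this scale understate the difference of genes with low values. Genes were compared when both values were above 0 and their mean was at least 1 FPKM. Genes listed at exactly 0 in 1 genotype were given no fold, since a 0 in such a table can be a failed estimate.

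Gene names came from a RefSeq table of the assembly Zm-B73-REFERENCE-NAM-5.0, which was used for names alone. Of 39604 identifiers, 18539 matched 1 entry, 521 matched several and were left unnamed, and 2682 received an informative name. Coordinates are those of the deposited table. Because that RefSeq table holds no descriptions, the lists defined beforehand by description were filled by patterns of gene names. The patterns were written before any list median was computed, but after the largest differences of single genes had been seen. Symbols can be shared by unrelated genes, so a list may hold members that its name does not describe. Members were counted as identifiers, and several can carry the same name, so a count may exceed the number of distinct genes. Lists for ribosome biogenesis, organellar ribosomal proteins and transposon-derived genes could not be filled that way. A further 10 lists were added after the table had been seen. For some list members the name came from the list fixed beforehand and not from the RefSeq table; these are given by identifier.

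The median of each list with at least 5 compared members was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. This percentile describes these values and is not a test across plants. Lists were singled out below the 2.5 or above the 97.5 percentile. The percentile step was tested on simulated differences for the 21057 compared genes, drawn independently from a normal distribution scaled to the quartiles of the data. With 1000 random lists each, lists of 30 genes shifted by 0.3 on the log2 scale fell outside that range in 100 of 100 draws. Lists of 10 genes with that shift did so in 85, lists of 30 genes shifted by 0.15 in 74, and unshifted lists of 30 genes in 4. Real genes of a list can vary together, so these rates need not hold for the data. Genes around HDA108 were taken as the 200 nearest compared genes on either side, and windows of the same number of genes on other chromosomes served as the comparison. Genes were counted as detected in 1 genotype alone, by the listed values, when the value there was at least 1 FPKM and that in the other genotype was below 0.1. Intervals of shares are exact 95% binomial intervals over genes, which are not independent replicates.

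Named genes were HDA108, the 12 named genes with the largest 2-fold differences in each direction (at most 3 of a family), the 2 largest of any gene, members of the lists singled out (up to 4), up to 2 members of the deacetylase, flowering, meristem, silencing and anther lists, and the 3 highest named genes detected in 1 genotype. Other genes named were chosen after their values were seen. Alternatives covered the pseudocount, the filter on low values, 3 scalings, window size and detection limits, with others added later. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.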

Results

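Transcript levels in developing leaves of the hda108 mutant were compared with those of wild type, from 3 libraries of each genotype. The deposited table lists 39604 genes with the authors' value for each genotype. The values summed to 478867 FPKM in wild type and 482019 FPKM in hda108, and 21057 genes could be compared. There is no replicate check of any difference, and the depth is unknown.

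HDA108 itself (GRMZM2G136067, chromosome 4, 65983217 to 65988818, B73 RefGen_v3) was lower in the library pool labelled hda108. The authors' value was 10.9 FPKM in wild type and 3.06 FPKM in the mutant, 28.1% of the wild-type value, a log2 difference of -1.68. Of the other deacetylase genes, hda106 had 1.86 FPKM in wild type and 3.70 FPKM in hda108, a difference of 0.83. The 9 compared genes of the deacetylase list had a median difference of 0.03, which lay at the 39.5 percentile of matched lists and was -0.03 with the median difference of all genes set to 0.

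Which transcripts differed in the mutant leaf was the main comparison. The ethylene response factor genes EREB36 and EREB65, the MADS-box gene m15 and the terpene synthase gene tps23 stood among the largest named differences upward. The annexin gene Ann5, bx1 of the benzoxazinoid pathway and the C4 photosynthesis gene pdk1 stood among those downward. At least 2-fold higher values in hda108 were listed for 311 genes and at least 2-fold lower values for 176 genes, so that 63.9% of the 487 genes were higher. The median difference of all compared genes was 0.06 and 91.1% of genes lay within 1.5-fold. With quantile normalization 55.1% of the genes past 2-fold were higher.

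Among named genes, EREB36, an ethylene response factor gene on chromosome 7, had 2.92 FPKM in wild type and 16.3 FPKM in hda108, a 4.92-fold difference. EREB65 on chromosome 2 was 4.66-fold higher, at 3.55 FPKM in hda108. The terpene synthase genes tps23 and tps10, both on chromosome 10, were 4.43-fold and 2.98-fold higher. The starch branching enzyme gene ae1 (GRMZM2G032628) had 0.352 FPKM in wild type and 3.18 FPKM in hda108. MADS-box genes also belonged to this group. The gene m15 (MADS15) had 3.84 FPKM in wild type and 18.1 FPKM in hda108, MADS36 was 3.32-fold higher and m31 was 2.95-fold higher. The others were phytase2 (3.33-fold), ARGOS4 (3.15-fold), ysl11 (2.78-fold) and Natterin-4 (GRMZM2G134264), which had 116 FPKM in wild type and 319 FPKM in hda108. None of these 12 genes lay on chromosome 4. Of them, m31 (6925446 to 6932461) and m15 (6993293 to 7011505) lie near each other on chromosome 5. In the first 10 Mb of that chromosome, which holds both, 13 of 339 compared genes were at least 2-fold higher and 0 lower (3.83%). Over the whole of chromosome 5, 41 were higher and 17 lower among 2550 (2.27%). Whether the first 10 Mb stands out was not tested.

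In the other direction, the annexin gene Ann5 on chromosome 4 had 9.83 FPKM in wild type and 1.58 FPKM in hda108. It was 4.97-fold lower on the scale of FPKM + 0.5. The gene bx1, which encodes the enzyme that makes indole for benzoxazinoid defence compounds, was 4.52-fold lower and also lies on chromosome 4. The gene bss1 had 36.4 FPKM in wild type and 8.86 FPKM in hda108. The thiamine biosynthesis gene thi1 had 167 FPKM in wild type and 52.8 FPKM in hda108. The expansin gene expB7 was 2.92-fold lower, the terpene synthase gene TPS5 (GRMZM2G074309) 2.74-fold lower, and the catalase gene cat2 and the gene pOMT1 each 2.65-fold lower. CNX5 (GRMZM2G157836) on chromosome 4 was 2.61-fold lower, the sucrose phosphate synthase gene sps1 2.56-fold lower, MYBR115 2.48-fold lower and pdk1 2.44-fold lower. Of any gene, the largest differences with the pseudocount of 0.5 were GRMZM2G456422 (chromosome 4, 126906995 to 126907839; 15.5-fold) and GRMZM2G088413 (chromosome 1, 254478909 to 254482162; 11.6-fold) upward. Downward they were AC155610.2_FG009 (chromosome 3, 175744245 to 175747343; 12.4-fold) and GRMZM2G040508 (chromosome 4, 138657354 to 138661148; 11.0-fold). AC155610.2_FG009 shares its locus entry with another gene, so its value is uncertain. Folds and order of genes with a low value depended on the pseudocount. With 0.1, GRMZM2G088413 (log2 difference 4.85) passed GRMZM2G456422 (4.62), EREB65 (2.96) passed EREB36 (2.44), and AC155610.2_FG009 had -5.67.

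Photosynthesis genes were lower in hda108. All 8 compared genes of the C4 list were lower, with a median log2 difference of -0.95, below all 10000 matched lists. That list also holds the rubisco small subunit gene rbcs1 (-0.74) and the rubisco activase gene rca1 (-0.82), which are not C4 enzymes. Pyruvate phosphate dikinase, pdk1, had 1111 FPKM in wild type and 455 FPKM in hda108. The NADP-malic enzyme gene me3 had 384 and 196 FPKM, and the phosphoenolpyruvate carboxylase gene pep1 had 167 and 85.6 FPKM, in wild type and hda108. The largest difference was that of GRMZM2G001696, listed beforehand as pck1, with 73.3 FPKM in wild type and 27.5 FPKM in hda108. The light-harvesting and photosystem list had 14 of 15 members lower, with a median of -0.36 at the 0.015 percentile and none past 2-fold; with quantile normalization the median was -0.21 (0.305 percentile). Its largest differences were cab-m1 (-0.52), lhcb4 (-0.49), psah1 (-0.45) and PSA2 (-0.41).

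Clock genes differed in both directions. GRMZM2G014902 and GRMZM2G474769, listed beforehand as lhy1 and cca1, were higher in hda108, the former at 9.05 FPKM in wild type and 23.8 FPKM in hda108 and the latter at 13.9 and 21.8 FPKM. GRMZM2G020081 and GRMZM2G148453, listed as toc1 and prr1, were lower, at 3.14 FPKM in wild type and 1.32 FPKM in hda108 for the former and 3.30 and 1.79 FPKM for the latter. The median over 5 members was -0.31 (1.255 percentile), and the genes listed as lhy1 and toc1 lie on chromosome 4.

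**Figure D1:**
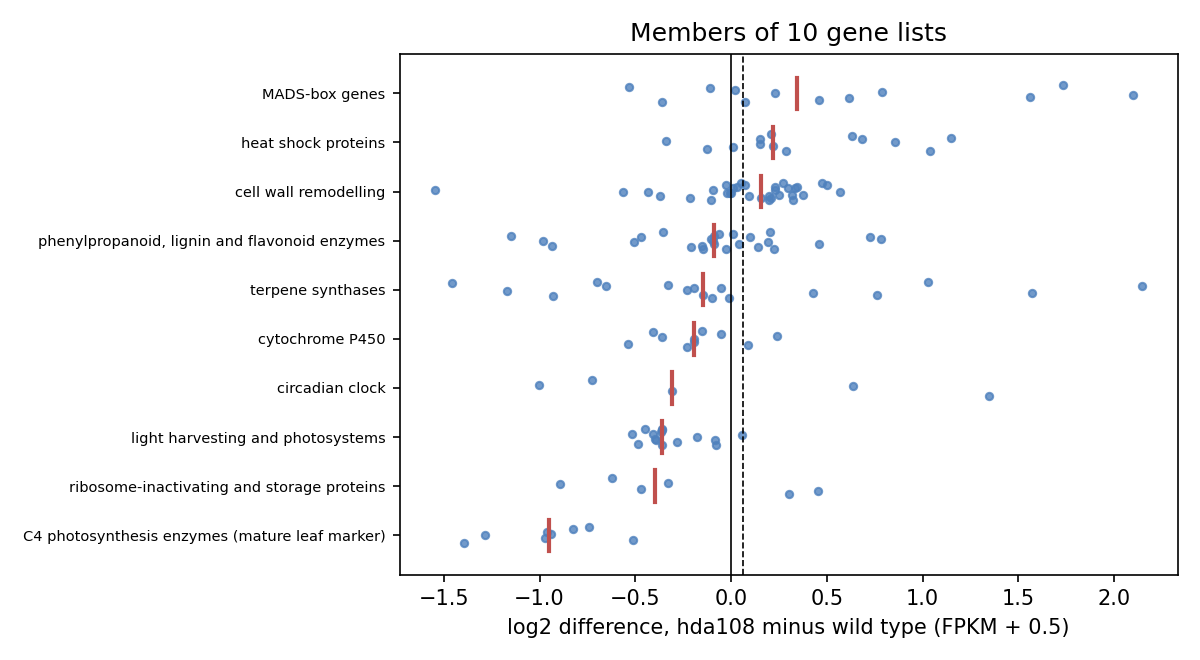
Log2 difference of FPKM + 0.5, hda108 minus wild type, on the horizontal axis, for each compared member (blue points) of the 10 lists singled out, with the list median as a red line; the solid line is 0 and the dashed line the median of all genes (0.06). All 8 genes of the C4 list lie below 0, while the members of the terpene synthase list lie on both sides.

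Of 31 lists whose subjects were fixed beforehand and that had enough members, 10 lay outside the range. By chance 1.55 would be expected if genes varied independently. Genes of a list can vary together between any pools of plants, which can raise that number without an effect of genotype. Many of the lists were also filled by name patterns after the largest single differences had been seen, so 10 is no independent count. MADS-box genes had 9 of 12 members higher, with a median of 0.34 (99.7 percentile); among genes with a mean of at least 5 FPKM that list lay at the 75.2 percentile, and without a filter at the 92.8 percentile. Heat shock protein genes had 11 of 13 members higher and a median of 0.22 (98.2 percentile). Among them hsp101, a chaperone gene, was 2.22-fold higher, hsp22 on chromosome 4 was 2.05-fold higher, Hsp70 1.81-fold and hsp3 1.61-fold. Cell wall genes had 22 of 33 members higher and a median of 0.16 (98.3 percentile). Examples were expA4 (0.57) and Cel26 on chromosome 4 (0.50), while expB7 (-1.54) and xet1 (-0.56) were lower. That list lay at the 93.4 percentile without chromosome 4 and at the 67.3 percentile without a filter on low values.

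The terpene synthase list, filled mainly by the symbol TPS, had 12 of 17 members lower (median -0.14, 0.92 percentile), although its largest differences were upward. That symbol is also used for trehalose phosphate synthases and was carried by several unrelated loci, so the list cannot be read as terpene synthases alone. Of its genes named TPS9, GRMZM2G122231 was 2.25-fold, GRMZM2G312521 1.62-fold and GRMZM2G465812 1.15-fold lower. The list lay at the 4.18 percentile among genes with a mean of at least 5 FPKM. Cytochrome P450 genes had 8 of 10 lower (median -0.19, 0.85 percentile), with CYP92C5 at -0.54, CYP714B3 at -0.41, dwarf3 at -0.36 and BX5 at 0.24. Of these 10, 4 lie on chromosome 4. Phenylpropanoid, lignin and flavonoid genes had 15 of 25 lower (median -0.09, 1.475 percentile). The lignin methyltransferase gene CAOMT, on chromosome 4 and sharing its locus entry, had 306 FPKM in wild type and 138 FPKM in hda108. The laccase gene lac5 had a difference of -0.98. Of the genes named Laccase-17, GRMZM2G305526 had -0.94 and GRMZM2G072808, the more abundant at 21.4 FPKM in wild type, had -0.11. The gene bronze1 of the anthocyanin pathway had 0.78. This list lay at the 15.2 percentile among genes with a mean of at least 5 FPKM and at the 4.43 percentile without shared locus entries. The list filled by name for storage and ribosome-inactivating proteins had 4 of 6 members lower (median -0.40, 0.10 percentile). The lower members were RAB15 (-0.90), rip2 (-0.62), GLB1 (-0.47) and RIP1 (-0.33). Higher were dhn2 on chromosome 4 (0.46) and dehydrin7 (0.30). The synonyms of GLB1 name a haemoglobin and not a storage globulin, and RAB15 was placed here by its name alone. The shift therefore cannot be read as one of storage and ribosome-inactivating proteins. Without a filter on low values the median of this list was 0.15 (93.5 percentile).

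Of the lists inside the range, core and linker histone genes had 10 of 11 members higher (median 0.13, 84.7 percentile). In these counts, higher means above 0, while the median difference of all compared genes was 0.06. Small RNA silencing genes had 10 of 13 higher (median 0.15, 86.5 percentile), with the genes named argonaute6 at 0.46 (GRMZM2G347402) and 0.36 (GRMZM2G432075) and rmr2 at 0.37. Several of the higher identifiers carry the name dcl4, so these are not all distinct names. Among maize silencing genes, GRMZM2G092497, listed as dmt103 and sharing its locus entry, had -0.87. Cytosolic ribosomal protein genes had 22 of 36 lower (median -0.03, 5.94 percentile) and jasmonate genes 18 of 35 lower (median -0.02, 7.06 percentile, and 51.2 without chromosome 4). Cell cycle genes had 23 of 32 higher (median 0.08, 63.0 percentile). Ethylene response factor genes had 18 of 27 higher and 4 of them past 2-fold (median 0.18, 96.5 percentile); among genes with a mean of at least 5 FPKM the list lay at the 99.95 percentile. The benzoxazinoid list, in which bx1 was the 1 member past 2-fold, had a median of 0.07 (56.1 percentile). The flowering, meristem and anther lists had fewer than 5 compared members and were not placed. Without a filter on low values the flowering list lay at the 1.17 percentile. Of the flowering regulators, ZCN8 had 1.68 FPKM in wild type and 0.863 FPKM in hda108, and conz1 differed by 0.27. The meristem gene fea2 differed by 0.02. In the anther list, cpi2, a cystatin gene by its synonyms, had a difference of 0.66 and mfs2, on chromosome 4, of -0.58.

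Whether differences gathered around the mutated gene was asked next, because a mutant can carry a chromosome segment along with the mutation. Of the 400 genes around HDA108, between 36017187 and 120915541 on chromosome 4, 21 (5.25%) differed at least 2-fold, 9 higher and 12 lower. The share was 2.25% among all other genes. The highest share in any window of that size on another chromosome was 4.75%, on chromosome 10. With 50 genes on either side the share was 6%, below the 9% of the highest window on chromosome 10, and with 400 it was 7.12%, above the 3.38% of the highest other window. Over the whole of chromosome 4, 49 genes were at least 2-fold higher and 51 lower among 2099, a share of 4.76%. Outside it, 262 were higher and 125 lower among 18958, a share of 2.04%, of which 67.7% were higher. The share varied along the chromosome. It was 7.34% between 60 and 100 Mb, where HDA108 lies, 7.95% between 100 and 140 Mb and again between 140 and 180 Mb. It was lower between 40 and 60 Mb, with 1 of 65 and 1 of 49 genes in the pair of 10 Mb bins, and beyond 210 Mb, with 6 of 443 genes. Ann5, CNX5 and HDA108 itself are among the chromosome 4 genes that were lower. The gene bx1 was also lower, but it lies at 3260761 to 3263006, in the first 20 Mb, where the share was 2.29%.

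**Figure D2:**
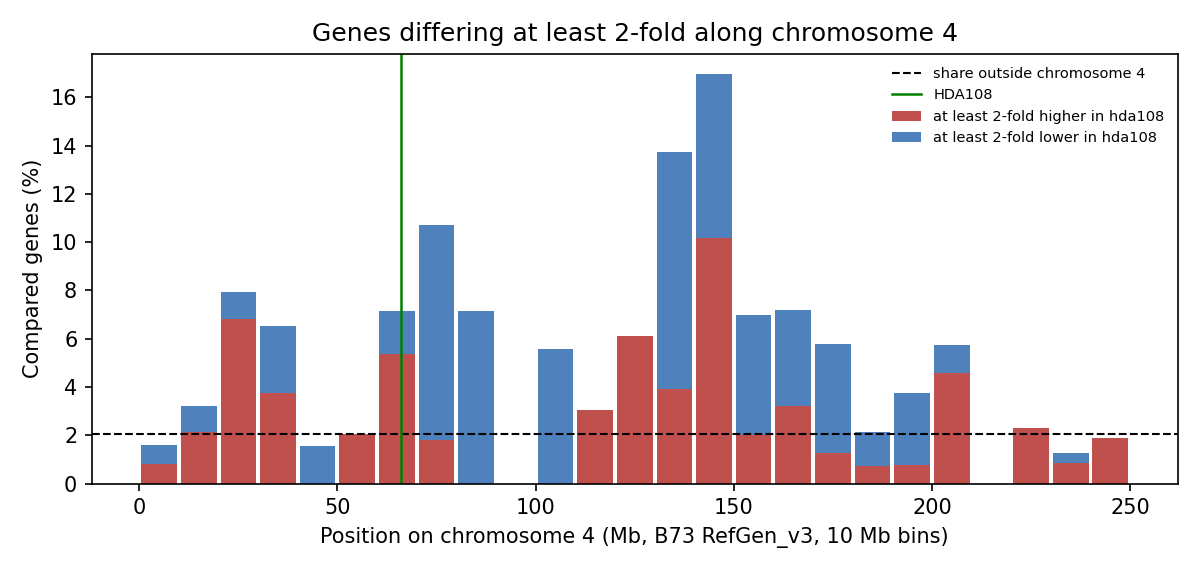
Share of compared genes at least 2-fold higher (red) or lower (blue) in hda108 in 10 Mb bins of chromosome 4, with position in Mb on the horizontal axis and percent of genes on the vertical axis; the dashed line is the share outside chromosome 4 (2.04%) and the green line marks HDA108. The parts between 140 and 180 Mb (7.95%) lie above the dashed line and the part beyond 210 Mb as a whole, with 6 of 443 genes, below it.

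Genes that met the rule for detection in 1 genotype alone were few, and those with names were microRNA precursors. Listed zeros were far more common: 10388 genes were at 0 in wild type and 9787 in hda108, with 8835 at 0 in both. Most of these entries rest on a listed 0, which can be a failed estimate and does not show that the transcript was absent. Values of at least 1 FPKM in hda108 and below 0.1 in wild type were listed for 35 genes, of which 26 were listed at 0 in wild type and 7 lie on chromosome 4. In the other direction there were 16 genes, of which 9 were listed at 0 in hda108 and 8 lie on chromosome 4. The highest named genes were MIR168b (158 FPKM), MIR167e (34.8 FPKM) and MIR394a (10.2 FPKM) in hda108. In wild type they were MIR398a (6.81 FPKM), MIR169b (2.30 FPKM) and MIR164g (1.47 FPKM). Each of these was listed at 0 in the other genotype. MIR394a and MIR398a share their locus entries with other genes, so their values are uncertain.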

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

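The tests of time of day, leaf maturity, long loci and direction on chromosome 4 were chosen after the results were seen. Those of the 1.5-fold to 2-fold genes, of matched loci and of scaling were fixed before their values were known, with bounds of 20 and 210 Mb taken from the genes past 2-fold.

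A signal in values left out of the fold comparison was listed for 8 genes at 0 in wild type and at 10 FPKM or more in hda108. These were GRMZM2G455413 (2764 FPKM), the plastid genes GRMZM5G813608 (2706 FPKM) and GRMZM5G856777 (2634 FPKM), which share a locus entry, MIR168b (158 FPKM), GRMZM2G498613 (81.1 FPKM), MIR167e (34.8 FPKM), GRMZM2G019085 (10.7 FPKM) and MIR394a (10.2 FPKM). MIR394a also shares its locus entry with another gene. No gene was listed the other way round at that level. Of genes at 10 FPKM or more in hda108, 6 of 646 in loci under 400 bp or with a shared entry were listed at 0 in wild type, and 2 of 8279 elsewhere.

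Genes past 2-fold were concentrated on chromosome 4. Matched on expression and span, 100 genes were observed against 42.3 expected, a ratio of 2.36 (95% Poisson interval 1.92 to 2.87). That interval takes genes as independent and the expected number as exact, and neither holds. The ratio argues against short or weakly expressed loci as the whole cause, but its spread between pools of plants is unknown. Between 20 and 210 Mb, 10.4% of genes differed by 1.5-fold to 2-fold, against 6.39% outside chromosome 4, a ratio of 1.63, but these bounds were taken from the genes past 2-fold, so the ratio restates the pattern. A linked segment from another background and an effect of losing HDA108 on genes of this chromosome cannot be told apart in this design; 49% of its genes past 2-fold were higher (interval 38.9% to 59.2%).

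Outside chromosome 4, 67.7% of the genes past 2-fold were higher in hda108. The scaling that lowered this most left 58.9% (interval 53.7% to 63.8%). That interval treats genes as independent replicates, which they are not. Scaling was also not tested together with locus length and expression, so scaling as the whole cause stays open. At loci of at least 1600 bp with a mean of at least 5 FPKM, 49 genes were higher and 34 lower, 59.0% (interval 47.7% to 69.7%), so noise at short or weak loci stays open. Loss of the deacetylase may raise transcripts, but pooled values cannot be told apart from differences between the sampled plants.

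C4 photosynthesis and light-harvesting genes were lower in hda108, and the C4 median of -0.95 stayed below 0 in each of the 3 scalings, as did that of the light-harvesting list, which was -0.21 with quantile normalization. Harvest at another time of day may contribute. Morning clock genes had a mean difference of 0.99 and evening ones of -0.86, 1.86 apart. These means come from 2 genes each, whose names rest on the list fixed beforehand. Whether such a clock difference goes with lower photosynthesis genes was not tested. Of each pair, 1 gene lies on chromosome 4 (lhy1 and toc1); the others, cca1 and prr1, differed by 0.64 and -0.73. The cell cycle list lay at the 63.0 percentile, which does not decide on leaf maturity, since cells past division also mature. With pooled values, harvest time, a less mature leaf sample and an effect of HDA108 on clock or photosynthesis genes cannot be told apart.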

How the results depend on the processing

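No paired analysis was possible because the table holds 1 pooled value per genotype; for the same reason the replicate block, leaving out libraries, eBayes without a trend, arrayWeights, camera with an estimated correlation, fry and the unadjusted p were not run. The settings without chromosome 4, short loci or shared entries, with genes listed at 0, or with a 1.5-fold rule were chosen after seeing the data. Depth is unknown, and the cause of the shifts below was not tested unless the setting itself gives it.

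HDA108 stayed lower in each setting that kept it, at -1.80 with a pseudocount of 0.1, -1.55 with 1, -1.74 with quantile normalization, -1.72 with upper quartile scaling and -1.74 with the median difference set to 0. With a mean of at least 5 FPKM, which leaves fewer genes, 133 genes were higher, 93 lower and 226 past 2-fold, 58.8% of them higher. The share higher was 55.1% with quantile normalization, 58.8% with upper quartile scaling and 56.5% with the median difference set to 0. A 1.5-fold rule, which admits smaller differences, gave 1120 genes higher, 764 lower and 1884 in all. It took in 14.8% of the genes near HDA108 and 8.83% of all other genes, a ratio of 1.67 against 2.33 with the 2-fold rule. Genes detected in hda108 alone numbered 75 with limits of 0.05 and 0.5, 22 with 0.2 and 2, 9 without genes listed at 0 and 20 without loci under 400 bp. For wild type alone these were 30, 5, 7 and 8, and 8 without chromosome 4. The storage protein list had a median of 0.15 in place of -0.40 without the filter on low values. The number of lists outside the range was between 8 and 11, not always with the same lists. The flowering list entered at the 1.17 percentile without a filter, leaf polarity at 98.5 and ethylene response factors at 99.95 with a mean of at least 5 FPKM, and the latter at 97.9 with quantile normalization. The clock list had too few members to be placed with a mean of at least 5 FPKM or without chromosome 4.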

Other observations

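The lists described here were added after the table had been seen. None of the 9 with enough members lay outside the range as first computed. The microRNA precursors, with 6 compared, lay at the 22.7 percentile but at the 0.13 percentile without chromosome 4, 99.5 without shared locus entries and 100 with genes listed at 0 in 1 genotype, so their place was not stable. The aquaporins lay at the 99.4 percentile among genes with a mean of at least 5 FPKM and at the 3.52 percentile without a filter on low values. Starch and sucrose genes had 12 of 26 members higher (median -0.02, 8.98 percentile), with ae1 and sps1 past 2-fold in opposite directions. Aquaporin genes had 11 of 22 higher (median 0.03, 35.4 percentile); tip4a had 33.7 FPKM in wild type and 14.3 FPKM in hda108, and sbip1b had 5.44 and 11.3 FPKM. Antioxidant enzyme genes had a median of -0.01 (18.5 percentile), with cat2 the 1 member past 2-fold. Among microRNA precursors above 0 in both genotypes, MIR390a was 2.58-fold higher in hda108 and MIR164c and MIR169j, which shares its locus entry, were each 2.02-fold lower.

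Of the ethylene response factor genes, EREB92 had 17.8 FPKM in wild type and 47.0 FPKM in hda108, DBP4 was 2.45-fold higher and dbf1 1.94-fold higher. Genes of the mitochondrial genome had a median difference of 0.28 over 46 genes and those of the plastid genome -0.12 over 25 genes.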
